A study of Mus musculus with 2 samples.

How the data were processed

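The series comprised 2 total RNA-seq libraries of C57BL/6NCrl mouse forebrain at embryonic day 11.5, which the labels number as biological replicates 1 and 2. Per the labels, they came from separate tissue collections of 109 and 88 embryos of mixed sex, RNA was extracted with the mirVana kit, 10 ng of RNA above 200 nucleotides entered each library, spike-in RNAs were added and a SMART-seq protocol was followed. Per the deposited text notes, reads were aligned to mm10 and to its transcriptome with the GENCODE M4 annotation. The aligner, the quantifier and their versions, read filters and the handling of strand are not given in the sources used here.

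The deposited tables hold expected counts per gene and per transcript, which are estimated by dividing reads that fit several transcripts and so need not be whole. The deposited TPM are length-scaled abundances over all entries of a table, spike-ins included, and the deposited FPKM are fragments scaled by length and depth. Per the file headers, the gene tables also hold a posterior mean TPM and the bounds of a credibility interval whose level the files do not state. Because short transcripts divide few reads by a small effective length, their TPM are less certain than those of long ones.

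Gene names, types, coordinates and GC content were taken from GENCODE M21 of the same build (GRCm38, mm10) by stable gene identifier, and 42462 of 43346 Ensembl identifiers (98.0%) matched. The other 884 held 0.232% and 0.231% of expected counts in replicates 1 and 2 and stayed in the gene-level tests under their identifiers. Entries with a numeric identifier (26248) and 97 spike-in entries stayed out of library sizes and tests, and spike-ins held 5.66% and 5.49% of counts. Annotated genes summed to 23165223 and 33597022 expected counts. Intervals and floors given in the text cover counting error only, and no molecular identifiers are described in the sources used here.

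There was a single group, so no comparison between groups was made. Expected counts were rounded to whole numbers for count tests. Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3 (factors 1.00 and 0.999), and edgeR's common dispersion was estimated over genes with 10 or more counts summed. Size factors of DESeq2 1.42.0 were an alternative. The libraries were compared per gene with an exact two-sided binomial test given the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 over genes with 10 or more counts summed, and log2 ratios used a prior of 0.5 counts. With 1 library on each side this test measures the difference between these libraries, of which each is a pool.

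Gene lists were fixed before the data were examined: 35 lists of regional, cell type, pathway and control genes and 1 list of 15 genes for isoforms. Of their members, Ahsp, Rn7sl1 and Rn7sl2 had no match by symbol and were not used here. List levels are medians of log2(TPM + 1) averaged over the libraries, set against 10000 random lists of the same size from protein-coding genes. The 4 planned list comparisons used a two-sided permutation of genes with 100000 resamples and adjustment over the 4. List shifts are medians of log2 ratios over members with 10 or more counts summed, set against 10000 random lists drawn from 20 expression bins. Isoform shares are a transcript's TPM over the summed TPM of its gene. Whole expected counts were those within 0.005 of a whole number in both libraries.

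Genes named in the text followed a rule fixed in advance. It took the 20 nuclear protein-coding genes of highest mean TPM, the 4 highest members of each list, and for lists of other tissues or later cell types the members at 5 TPM or more in both libraries, up to 10. It further took the 10 genes with the largest difference in each direction among those past the test with at least 2-fold and 100 or more counts, and isoforms with 20% or more of their gene. Other named genes (Gfap, Alb, Lhx6, Dlx6, Lhx8, Sp9, Nkx2-1, Isl1, Gad2, Aldh1a3, Mitf, Gm28437, Gm10123 and those of the closing section) were chosen after their values were seen. Some genes that the rule took are not named here.

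The steps were tested on simulated data. With Poisson counts drawn at the real means and library sizes and 200 genes changed 4-fold, the library difference recovered 100% of them with 4 false calls among 18258 genes at 2-fold or more. That simulation held no spread beyond counting. In the real libraries the variance was 2.16 times that of counting at 10 to 100 counts and 20.2 times at 10000 or more. The number of false calls in the simulation therefore does not carry over to these data. A ventral telencephalon list shifted by -0.42 log2 units returned a median of -0.38, and 2 of 33 unchanged lists fell outside the central 95%, in a run on 18280 genes. Simulated coefficients of variation of 0.05, 0.1 and 0.2 were estimated as 0.05, 0.0995 and 0.200. In the permutation step, 1 of 40 pairs of lists drawn without a difference gave p under 0.05. Alternatives covered scaling, count and TPM filters, pseudocounts, FPKM and posterior mean TPM, gene classes, list summaries and leaving out each library. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.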

Results

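Total RNA was sequenced from forebrain of C57BL/6NCrl mouse embryos at embryonic day 11.5, when the telencephalic wall consists mostly of dividing neuroepithelium and the earliest neurons are being born. The series held 1 group of 2 libraries, each made from a separate pool of embryos of both sexes. Replicate 1 came from 109 embryos and replicate 2 from 88, and each library started from 10 ng of RNA longer than 200 nucleotides with added spike-in RNAs. The deposited gene tables gave 23165223 expected counts on annotated genes in replicate 1 and 33597022 in replicate 2. There was no second tissue, age or treatment, so the data describe which genes this tissue expressed and how far its 2 pools differed. Values are TPM, the length-scaled transcript abundance, as mean ± SD of the 2 replicates (n = 2) unless stated otherwise. Spike-ins took 12.8% ± 0.194 of all TPM, so the TPM of mouse genes are understated by that share.

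The most abundant nuclear protein-coding transcript was that of Hbb-y, an embryonic beta-like globin of primitive red cells, at 8401 ± 459.7 TPM (ENSMUSG00000052187.3, chromosome 7, 103851749 to 103853216, GRCm38). Cytoskeletal and housekeeping transcripts followed, with Actb at 4909.5 ± 309, Tuba1a at 4819 ± 480.3, Eef1a1 at 3735 ± 67.6, Ppia at 3768 ± 183 and Tmsb4x at 3242 ± 238 TPM. The same group of 20 highest genes held chromatin and cell cycle transcripts, among them Hmgn2 at 3429 ± 143, H2afz at 2594 ± 188, H3f3a at 2468 ± 18.8 and Cdk4 at 2338 ± 43.9 TPM, and the microtubule regulator Stmn1 at 2482 ± 9.44 TPM. It also held the replication-dependent histone Hist1h2ap at 4943 ± 73.2 TPM, a transcript without a poly(A) tail, and the ferritin subunit Ftl1 at 3998 ± 110.0 TPM. The chaperone Hspa8 at 2819.9 ± 62.0, polyubiquitin Ubb at 2633 ± 113, Ptma at 2591 ± 108 and the ribosomal protein transcript Rpl41 at 2425 ± 17.2 TPM were the others outside the globins. Genes of this group with many processed pseudogenes or near-identical copies, such as Eef1a1, Ppia, Ubb, Rpl41 and the histones, share reads with those copies, and their values depend on how the quantifier divided them.

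TPM of 1 or more in both libraries was reached by 14241 of 43346 genes, including 12581 of 21474 protein-coding genes (58.6%). Among long non-coding genes 733 of 5694 were detected, and among pseudogenes 547 of 7906. A further 1183 genes passed in 1 library only. Nuclear protein-coding genes held 76.9% ± 0.126 of TPM, a value that was 89.4% as a share of expected counts, where long genes weigh more and short spike-ins less. Ribosomal protein genes held 5.12% ± 0.113 of TPM, pseudogenes 3.99% ± 0.102, mitochondrial genes 2.06% ± 0.0608, long non-coding genes other than Gm42418 and Gm26917 1.29% ± 0.0871 and replication-dependent histones 0.649% ± 0.00773. As shares of expected counts these classes held 1.95%, 1.17%, 0.968%, 0.934% and 0.163% in the same order. The long non-coding genes Gm42418 and Gm26917, which were kept apart from that class after their values were seen, held 1.13% ± 0.0124 of TPM and 1.48% of expected counts. Gm42418 is listed as another name of an 18S ribosomal RNA related sequence but is annotated as a lincRNA. Genes of the annotated ribosomal RNA type, which exclude it, held 0.00572% ± 0.00156. Among pseudogenes, Gm28437 at 4497 ± 29.0 and Gm10123 at 3310 ± 214 TPM had expected counts that were not whole. The pseudogene share, and the shares of classes whose reads fit pseudogenes, therefore depend on how the quantifier divided shared reads.

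The pools were close for well-covered genes. Across 15424 genes with TPM of 1 or more in either library, log2(TPM + 1) had a Pearson r of 0.984 and a Spearman rho of 0.986. These correlations are across genes, which are not independent replicates. Over protein-coding genes alone r was 0.994, and with a pseudocount of 0.01 it was 0.894. The common dispersion corresponded to a coefficient of variation of 7.63% between the pools beyond counting noise. The SD of the log2 ratio fell from 1.11 in genes with 10 to 100 counts summed over both libraries to 0.10 in genes with 10000 or more. In that last class the variance was 20.2 times that of counting alone, so the libraries were not a duplicated deposit. The 34 spike-ins with 1000 or more counts summed, which carry no biology, had an SD of 0.14. Mouse genes drawn to match their counts had an SD of 0.12 (95% of 1000 draws between 0.09 and 0.16), a range that includes the spike-in value.

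**Figure D1:**
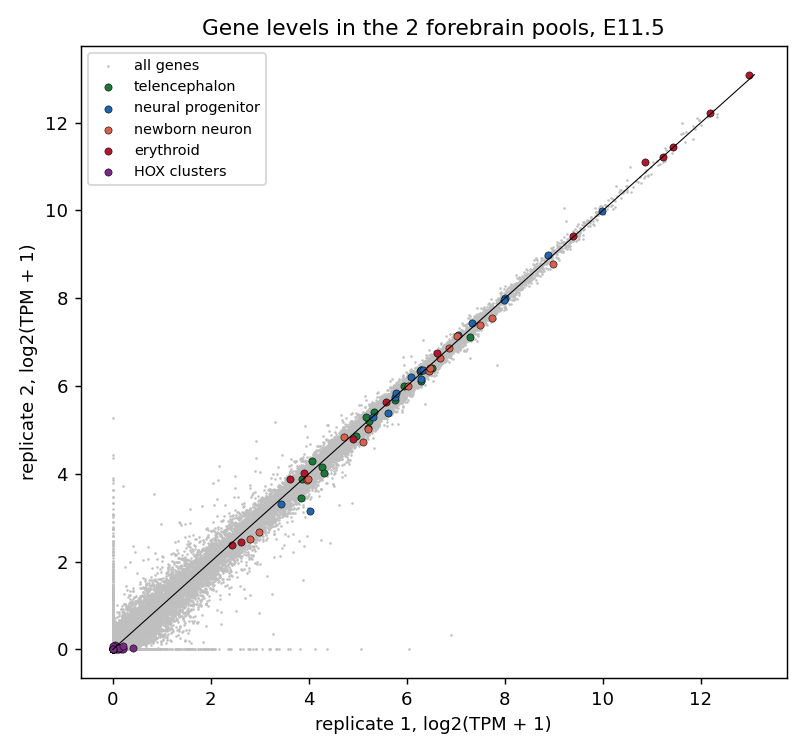
Level of each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2(TPM + 1), with all genes in grey, members of 5 gene lists in colour and the line of equality in black. The globins lie at the top right, the HOX genes lie at the origin, and the scatter widens below about 2 on both axes.

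The first comparison asked whether the dissected tissue carried anterior and not posterior patterning genes. All 17 genes of the telencephalon list were detected, led by Lhx2 at 147 ± 10.9, Nr2f1 at 87.5 ± 4.85, Pax6 at 78.9 ± 3.23 and Bcl11a at 78.0 ± 2.27 TPM, transcription factors of forebrain patterning and cortical identity. None of the 39 HOX genes, which pattern the hindbrain, spinal cord and trunk, reached 1 TPM. The highest mean of a HOX gene was 0.18 TPM. Other members with a count included Hoxd3 at 0.105 ± 0.0636, Hoxb5 at 0.0950 ± 0.0919 and Hoxb7 at 0.08 ± 0.113 TPM, and 23 HOX genes had no count in either library, which allows up to 3 counts per gene and library by counting error alone. The median of the telencephalon list was 5.23 log2 units above that of the HOX list (per-library difference 5.26 ± 0.0409, SD, n = 2). A two-sided permutation of genes between the lists gave p = 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 4.00e-05 over the 4 list comparisons. Genes, not embryos, were permuted in these comparisons, so the p-values describe the lists and not a population of animals. The telencephalon and HOX lists were chosen for their known regions, and no other tissue was measured. This p-value therefore does not measure how clean the dissection was.

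Neighbouring territories lay between these extremes. Of the diencephalon and hypothalamus list 16 of 16 members were detected, with Tcf7l2 at 114 ± 2.81, Fezf1 at 29.3 ± 1.47, Dbx1 at 25.4 ± 1.27 and Olig3 at 20.2 ± 1.75 TPM as the highest. In the midbrain and hindbrain list 3 of 12 members were detected, including the patterning signal Fgf8, also made by the anterior neural ridge, at 16.1 ± 2.02 TPM and Pou4f1 at 2.30 ± 0.962 TPM, while the midbrain factor En1 stood at 0.885 ± 0.0354 TPM. In the eye field list 4 of 12 members were detected, and by TPM the highest were Dct at 5.05 ± 0.813, Vax1 at 4.65 ± 0.0849, Pmel at 2.42 ± 1.59 and Rax at 2.36 ± 0.495. By posterior mean TPM, Mitf of the same list stood above all of these. Detection and ranking in this list therefore depend on which deposited estimate is used. Exons of Pmel overlap Cdk2 and Dgka on the opposite strand, and no source used here states that counting was by strand, so its reads cannot be assigned to Pmel with certainty.

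The second comparison set the pallium, or dorsal telencephalon, against the subpallium, or ventral telencephalon. Both lists were detected in full, with 14 genes each. The dorsal list was led by Pax6, Neurog2 at 72.3 ± 3.22, Emx2 at 61.5 ± 1.53 and Emx1 at 51.6 ± 2.12 TPM, genes of cortical progenitors. The ventral list included Dlx1 at 99.1 ± 8.32, Dlx2 at 53.1 ± 0.643 and Dlx5 at 36.5 ± 1.13 TPM, genes of the ganglionic eminences. Summed TPM of the dorsal list was 1.26 ± 0.111 times that of the ventral list. The dorsal median exceeded the ventral by 0.48 log2 units, 0.34 in replicate 1 and 0.60 in replicate 2. This difference did not pass the permutation test (two-sided permutation p = 0.298, adjusted p = 0.398).

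The comparisons of progenitor, newborn and mature genes described the state of differentiation. All 16 neural progenitor genes were detected, with the intermediate filament Vim at 1013 ± 3.95, the radial glial lipid carrier Fabp7 at 488 ± 24.7, Id4 at 255 ± 0.615 and the Notch effector Hes5 at 249 ± 2.66 TPM at the top. All 16 newborn neuron genes were detected too, with the neuronal tubulin Tubb3 at 473 ± 47.5, Crmp1 at 198 ± 18.1, Stmn3 at 174 ± 9.05 and Map2 at 134 ± 7.19 TPM. The medians of the lists differed by 0.07 log2 units, which did not pass the two-sided permutation test (permutation p = 0.884, adjusted p = 0.884). The difference of means in place of medians was 0.76 log2 units and did not pass either (permutation p = 0.232). Genes of mature synapses were lower: 10 of 12 members were detected, the highest being Snap25 at 14.5 ± 0.424, Dlg4 at 14.4 ± 1.71, Syt1 at 13.4 ± 0.290 and Gria2 at 11.4 ± 0.0636 TPM, followed by Syn1 at 9.54 ± 0.615 and Camk2a at 6.67 ± 1.82 TPM. The newborn neuron median was 3.75 log2 units above the mature synapse median (per-library difference 3.75 ± 0.187, SD, n = 2; two-sided permutation p = 5.00e-05, adjusted p = 1.00e-04). Tubb3 stood at 77.5 ± 5.47 times the level of Rbfox3, the antigen NeuN of later neurons.

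The cell cycle list stood high, with all 19 members at 5 TPM or more and a median of 7.63 on the log2(TPM + 1) scale. Its leading members were Rrm2 at 515 ± 18.5, Cdk1 at 364 ± 17.7, Top2a at 363 ± 16.5 and Ccnb1 at 361 ± 2.5 TPM. Of the Cajal-Retzius list, for the early-born neurons of the marginal zone, all 9 members were detected, with Nhlh2 at 26.5 ± 1.52, Calb2 at 22.9 ± 0.339, Lhx5 at 19.4 ± 1.48 and Ebf2 at 15.4 ± 0.516 TPM. Among 35 fixed lists, 12 had a median in the highest 2.5% of 10000 random lists of protein-coding genes of the same size, as a description of these libraries. The telencephalon, dorsal telencephalon, neural progenitor, cell cycle, newborn neuron, erythroid, imprinted, Notch, Wnt, Fgf, housekeeping and glycolysis lists made up that group. The ventral telencephalon list stood at percentile 96.0, mature synapse at 54.4 and the liver list at 2.89.

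**Figure D2:**
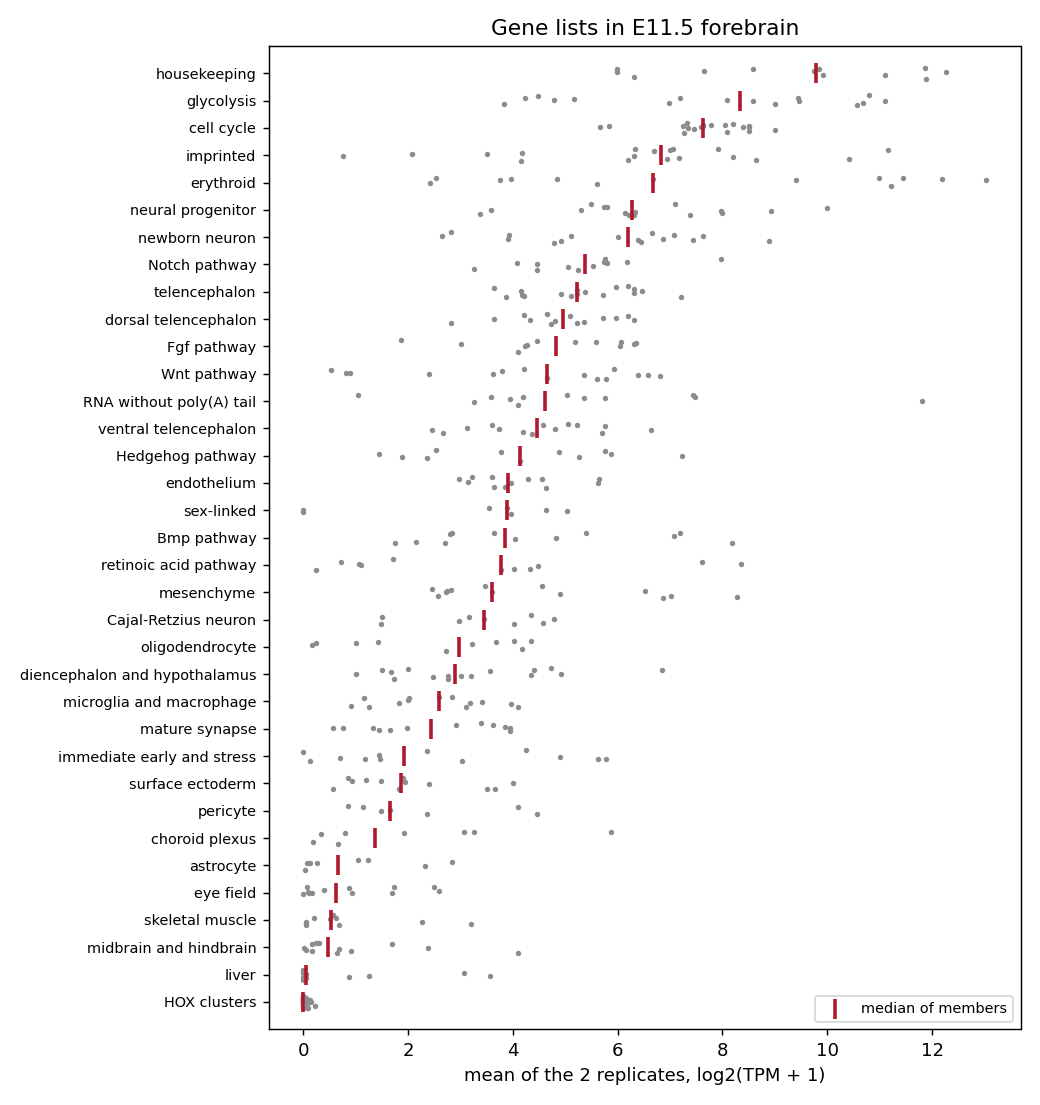
Mean log2(TPM + 1) over the 2 replicates (horizontal axis) of each member (grey points) of the 35 gene lists (vertical axis), with the median of each list as a red bar. Medians run from 0.000 for the HOX clusters to 9.79 for the housekeeping list.

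Markers of other tissues and cell types were measured in the same libraries. Erythroid genes were the most abundant, with 13 of 13 detected and 2.11% ± 0.0807 of all TPM in 7 globin genes. Besides Hbb-y they included Hba-a2 at 4694 ± 73.0, Hba-x at 2779.8 ± 38.4, Hba-a1 at 2379 ± 27.6, Hbb-bh1 at 2035 ± 249, Hbb-bt at 678 ± 8.39 and Hbb-bs at 102 ± 6.33 TPM, where the Hba-a1 and Hba-a2 pair is near-identical and its division uncertain. The embryonic beta-like globins Hbb-y and Hbb-bh1 together stood at 13.4 ± 0.657 times the adult beta globins. The haem enzyme Alas2 at 47.7 ± 1.10 and the membrane protein Slc4a1 at 27.9 ± 1.68 TPM were further red cell genes. Mesenchyme genes were detected in full (13 of 13), with Col3a1 at 309.8 ± 13.9, Col1a1 at 129 ± 0.382, Col1a2 at 116 ± 6.14 and Lum at 90.6 ± 1.68 TPM, and Alx1 at 28.9 ± 2.47, Prrx1 at 22.6 ± 0.290, Dcn at 11.2 ± 0.177, Twist1 at 10.1 ± 0.361, Foxc1 at 6.11 ± 0.488 and Postn at 5.70 ± 0.226 TPM below them. Endothelial genes were also detected in full (12 of 12), led by Ramp2 at 49.4 ± 2.64, Egfl7 at 48.5 ± 3.01, Esam at 23.9 ± 0.516 and Kdr at 22.6 ± 0.0283 TPM. Cldn5 at 18.5 ± 2.68, Emcn at 14.8 ± 2.33, Pecam1 at 13.5 ± 1.92, Cdh5 at 11.5 ± 1.53, Tie1 at 11.1 ± 0.495 and Flt1 at 8.31 ± 1.20 TPM followed. In the pericyte list 6 of 7 were detected, with Notch3 at 21.1 ± 0.481 TPM, Pdgfrb at 16.1 ± 1.44 TPM, Kcnj8 at 4.22 ± 1.07 TPM and Anpep at 2.18 ± 0.269 TPM. Microglia and macrophage genes were present at low level (12 of 13 detected), with C1qb at 16.1 ± 0.813, Fcer1g at 14.6 ± 0.0849, Tyrobp at 9.85 ± 3.19, C1qc at 8.15 ± 0.396, C1qa at 7.70 ± 1.70, Csf1r at 6.17 ± 0.00707 and Cd68 at 5.07 ± 0.0566 TPM.

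Genes of later glia were measured as well. In the oligodendrocyte list 7 of 10 were detected, and the highest were Olig2, a gene also expressed by ventral progenitors, at 19.6 ± 4.22 TPM, Pdgfra at 17 ± 1.53 TPM, Cnp at 15.2 ± 1.10 TPM, Mbp at 11.9 ± 0.438 TPM and Olig1 at 8.44 ± 1.90 TPM. In the astrocyte list 2 of 8 were detected, with Slc1a2 at 6.17 ± 0.113 TPM, Aldoc at 4.26 ± 2.31 TPM, Aldh1l1 at 1.42 ± 0.693 TPM and Gjb6 at 1.09 ± 0.339 TPM, and Gfap stood at 0.05 ± 0.0283 TPM. In the surface ectoderm list 9 of 12 were detected, with Krt8 at 15.2 ± 1.86, Epcam at 11.7 ± 0.346, Krt18 at 10.3 ± 0.969 and Cdh1 at 4.29 ± 0.332 TPM. In the choroid plexus list 4 of 8 were detected, with Otx2, a gene of the early forebrain and midbrain as well, at 57.6 ± 2.93 TPM, Folr1 at 8.65 ± 0.502 TPM, Ttr at 7.48 ± 0.990 TPM and Clic6 at 2.84 ± 0.566 TPM. Skeletal muscle (2 of 10 detected) reached 5 TPM in both libraries only with Mylpf at 8.18 ± 0.856 TPM, above Tnnt1 at 3.87 ± 0.792, Actc1 at 0.615 ± 0.0778 and Tnnc1 at 0.555 ± 0.134 TPM. The liver list (3 of 10 detected) did so only with Trf at 11.0 ± 2.08 TPM and Ttr, Apoa2 stood at 1.40 ± 0.163 TPM and Apoa1 at 0.84 ± 0.0990 TPM, and the hepatocyte product Alb had no count in either library.

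Signalling lists were detected broadly. The Notch list was complete (12 of 12), with Hes5, Dll1 at 71.7 ± 6.96, Notch1 at 54.9 ± 1.45 TPM and Hey1 at 53.6 ± 3.43 TPM. The Hedgehog list was complete (11 of 11) and led by Gas1 at 149 ± 3.72, Smo at 57.7 ± 2.98, Gli3 at 52.9 ± 0.509 and Sufu at 37.4 ± 0.368 TPM. In the Wnt list 12 of 15 were detected, with Wnt7b at 112 ± 4.01, Sfrp1 at 94.1 ± 0.297, Sfrp2 at 82.4 ± 2.84 and Rspo3 at 59.7 ± 4.20 TPM. The Fgf list was complete (12 of 12), with Fgfr3 at 80.2 ± 2.16, Fgfr2 at 78.3 ± 4.03, Fgfr1 at 66.0 ± 0.396 and Fgf15 at 64.9 ± 0.198 TPM. The Bmp list was complete (12 of 12), with Id3 at 289 ± 16.1, Id2 at 145 ± 7.53, Msx1 at 134 ± 6.09 and Id1 at 41.2 ± 1.14 TPM. In the retinoic acid list 8 of 11 were detected, with the binding proteins Crabp2 at 326 ± 4.39 and Crabp1 at 195 ± 31.4 TPM far above Rara at 19 ± 1.29 TPM.

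Imprinted genes were prominent, with 17 of 18 detected and Nnat at 2299.7 ± 140.4, Mest at 1358 ± 12.5, Meg3 at 401 ± 11.7 and Ndn at 294 ± 22.8 TPM as the highest. The Nnat gene is ENSMUSG00000067786.12, chromosome 2, 157560078 to 157562522 (GRCm38). Glycolytic genes were detected in full (16 of 16), led by Gapdh at 2212 ± 96.3, Pkm at 1770.1 ± 98.6, Ldha at 1633 ± 56.5 and Eno1 at 1523 ± 66.8 TPM, and the housekeeping list was complete (12 of 12). Of the immediate early and stress list 9 of 12 were detected, with Ier2 at 53.8 ± 0.778, Jun at 48.7 ± 1.10, Dusp1 at 28.9 ± 1.20 and Ddit3 at 18.1 ± 1.12 TPM. Transcripts that lack a poly(A) tail were present (12 of 12 detected), with Malat1 at 3602 ± 643, Rn7sk at 176 ± 7.95, Hist1h2ae at 174 ± 6.80 and Rpph1 at 53.4 ± 8.23 TPM. Both sexes were represented, with Xist at 24.0 ± 1.90 TPM and the Y-linked genes Eif2s3y at 31.9 ± 5.39, Kdm5d at 14.7 ± 1.62 and Ddx3y at 14.2 ± 4.36 TPM, while 5 of 7 members of that list were detected. Exons of Nnat, Mest, Meg3, Gapdh, Malat1, Xist, Dlx1, Emx2, Otx2 and Wnt7b, among others, overlap a gene on the opposite strand, so their values are uncertain to that extent.

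Transcript tables gave the isoform makeup of 15 genes chosen before the data were examined. In Pkm, the pyruvate kinase gene, the deposited tables listed a transcript with the downstream and a transcript with the upstream of a pair of mutually exclusive exons, each 167 nucleotides long. The transcript with the downstream exon (chromosome 9, 59675568 to 59675734), which encodes the PKM2 form of proliferating cells, is Pkm-201 and held 94.4% ± 0.355 of Pkm TPM. The transcript with the upstream exon (59675029 to 59675195), the PKM1 form of differentiated muscle and brain, held 5.56% ± 0.355. Single transcripts led Cdc42 (Cdc42-202, 91.4% ± 0.126), Tpm3 (Tpm3-201, 88.8% ± 0.117), Gnas (Gnas-208, 81.1% ± 2.44), Ncam1 (Ncam1-204, 78.5% ± 4.49) and Clta (78.3% ± 0.954 in its leading transcript). Snap25-201 held 65.0% ± 0.731 and Snap25-202 30.4% ± 1.48 of Snap25 TPM. Dcx was divided between Dcx-203 at 44.8% ± 2.33 and Dcx-201 at 39.5% ± 1.69, and Cltb between Cltb-202 at 53.9% ± 5.72 and Cltb-201 at 45.3% ± 5.68. Map2-201 held 45.6% ± 4.12 and Numb-204 and Numb-203 41.9% ± 7.03 and 28.9% ± 3.19. Pax6-202 and Pax6-207 held 26.7% ± 1.31 and 23.8% ± 5.76 of Pax6 TPM. In Ptbp1, a splicing repressor of neural exons, Ptbp1-202, Ptbp1-216 and another transcript held 32.1% ± 6.10, 29.6% ± 1.92 and 29.1% ± 7.36, and Ptbp2 TPM was 0.960 ± 0.0364 times that of Ptbp1. App and Ptbp2 had 1 transcript each in the deposited tables. Among 4645 genes with TPM of 10 or more and at least 2 transcripts at 10% or more, the leading transcript differed between the libraries in 454 (9.77%). By transcript expected counts the order in Dcx was the opposite, with 62.7% in Dcx-201 and 31.6% in Dcx-203. On that measure Cltb-202 held 72.1% and Cltb-201 26.4%, Snap25-201 72.6% and Snap25-202 15.4%, and the Ptbp1 transcripts 30.3%, 33.6% and 33.6%, so no Ptbp1 transcript led on both measures. These shares are the quantifier's estimates from reads that many isoforms share.

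The last comparison asked which genes differed between the pools beyond counting noise. It compares 2 libraries and not conditions. The genes below are those with the largest differences among genes with 100 or more counts. Higher in replicate 2 were Tom1, mt-Nd4l, Rpl21-ps15 and Gm20425, each with a count of 0 in replicate 1 and at least 43.8, 38.2, 38.2 and 31.6-fold higher against a floor of 3 counts per library. The lower 95% limits of their ratios, which also carry the counting error of replicate 2, were 35.2, 30.7, 30.7 and 25.3 (exact binomial intervals). Next came the zinc finger genes Gm14308 and Gm14440 of chromosome 2 (log2 ratios 2.13 and 1.67), the non-coding genes Gm26735 and Gm26789 (1.99 and 1.62), the pseudogene Gm2223 (1.81) and the palate gene Tbx22 (1.65). Lower in replicate 2 were Gm15725, with a count of 0 there and at least 67.1-fold lower against the same floor (upper 95% limit of the ratio 0.0186), Tmem254b (-6.16), Gm14434 (-3.76), Gm27000 (-2.56) and Nanp (-2.13). Zfp781, mt-Nd3, Gm20388, Gm8116 and Gm20458 had log2 ratios between -1.49 and -1.26. Among these 20 genes, only Tbx22 and Gm26789 had whole expected counts in both libraries, so the values of the other 18 depend on how shared reads were divided.

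An exact two-sided binomial test with Benjamini-Hochberg adjustment called 4296 of 18297 genes, and 481 of these differed at least 2-fold (271 higher and 210 lower in replicate 2). The test weighs counting error alone with 1 library on each side, and spike-ins varied with an SD of 0.14 in log2 ratio, so calls of about that size in single genes are not shown to exceed technical spread. With 50 or more counts summed the 2-fold count was 183, and with non-overlapping credibility intervals in place of the test it was 207. The balance was 114 higher and 69 lower with 50 or more counts and 130 higher and 77 lower with the intervals, but 129 higher and 133 lower over protein-coding genes only, so the excess of genes higher in replicate 2 did not hold for that class. Of the 74 genes called with at least 2-fold and 100 or more counts, 53 were higher in replicate 2, among them 15 loci of the class still to be experimentally tested (TEC) in the annotation, and 21 were lower, with no TEC locus among them. Protein-coding genes made up 24 of the 53 and 18 of the 21.

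By gene list, the ventral telencephalon genes were lower in replicate 2, with a median log2 ratio of -0.21, below all 10000 random lists of matched expression. Over that list there were 0 higher and 7 lower in replicate 2 over all genes tested, and 0 higher and 8 lower adjusted over the list alone. Those called over all genes included Lhx6 (-0.81, adjusted p = 8.25e-20), Dlx6 (-0.68), Lhx8 (-0.61, adjusted p = 4.32e-10), Sp9 (-0.58) and Nkx2-1 (-0.33) in the exact binomial test, of which Dlx6 and Sp9 overlap exons of a gene on the opposite strand and are uncertain to that extent. The drop did not hold for every member, as 11 of 14 were lower and 3 higher. Dlx2 (-0.04), Dlx5 (0.07), Isl1 (0.05) and Gad2 (0.01) were not called over all genes. Newborn neuron genes had a median of -0.11 (percentile 0.15), with 1 higher and 7 lower in replicate 2 over all genes tested, and 2 higher and 7 lower adjusted over the list alone. Among the lower members were Tubb3 (-0.21) and Crmp1 (-0.19). Glycolysis genes had a median of -0.10 (percentile 0.07), with 0 higher and 10 lower in replicate 2 over all genes tested, and 0 higher and 11 lower adjusted over the list alone. Among sex-linked genes, with 3 higher and 1 lower in replicate 2 over all genes tested, and 4 higher and 1 lower adjusted over the list alone, 4 Y-linked genes summed to 1.28 times the level of replicate 1 in replicate 2 (95% exact binomial interval 1.22 to 1.35) and Xist to 0.891 times (0.864 to 0.920).

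Retinoic acid genes had a median of 0.18 (percentile 98.6), with 2 higher and 1 lower in replicate 2 over all genes tested, and 2 higher and 1 lower adjusted over the list alone. Crabp1 (0.33) and the retinaldehyde dehydrogenase Aldh1a3 (0.76) were higher. Eye field genes had a median of 0.63 (percentile 99.6) over 8 members, with 2 higher and 0 lower in replicate 2 over all genes tested, and 2 higher and 0 lower adjusted over the list alone. These were Pmel (1.45), whose reads cannot be assigned to it with certainty, and Mitf (0.82). In posterior mean TPM Mitf went the other way, with 32.4 in replicate 1 and 23.5 in replicate 2, so its direction is uncertain. Its level and its rank in the list are uncertain too, since by TPM it was not among the detected members. Dct, the highest member by TPM, had a log2 ratio of -0.33 and was not called (adjusted p = 0.0891 in the exact test). Bmp genes (-0.13, percentile 1.31), imprinted genes (-0.06, percentile 1.75) and choroid plexus genes (-0.34, percentile 1.59) were the remaining lists outside the central 95%. There were 2 higher and 4 lower in replicate 2 over all genes tested, and 2 higher and 6 lower adjusted over the list alone for Bmp. The corresponding counts were 3 higher and 6 lower in replicate 2 over all genes tested, and 4 higher and 7 lower adjusted over the list alone for imprinted genes, and 0 higher and 1 lower in replicate 2 over all genes tested, and 0 higher and 0 lower adjusted over the list alone for choroid plexus genes. In all, 9 of 34 lists lay outside the central 95%, where 1.70 would if list members were as independent as randomly drawn genes. Members of a list can vary together, and some lists share members, such as Ttr and Pax6. With 1 library on each side, the excess over 1.70 is therefore not shown to exceed chance. When random lists were matched on GC as well, an alternative chosen after seeing the data, Bmp and imprinted genes came inside it at percentiles 4.61 and 4.55. Glycolysis genes went to percentile 2.13, near the limit, as the mean of random lists went from 0.01 to -0.04. With 50 or more counts choroid plexus genes came inside it at 3.79.

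The other lists with a percentile lay inside the central 95% as lists. The HOX list had none, since only 1 member was tested. Its 39 genes held 39 and 14 counts in replicates 1 and 2. Single members were called in each of the lists below except midbrain and hindbrain and skeletal muscle. The number of members called in the exact test over all genes, followed by the number adjusted over the list alone, was telencephalon 7 and 7, dorsal telencephalon 5 and 6, diencephalon and hypothalamus 4 and 9, midbrain and hindbrain 0 and 0, HOX clusters 1 and 1, neural progenitor 8 and 9, cell cycle 10 and 11, Cajal-Retzius neuron 3 and 5, mature synapse 2 and 1 for the regional and cell state lists. In the same order it was astrocyte 1 and 1, oligodendrocyte 4 and 4, microglia and macrophage 2 and 1, erythroid 5 and 5, endothelium 5 and 5, pericyte 3 and 3, mesenchyme 3 and 3, surface ectoderm 4 and 4, skeletal muscle 0 and 0, liver 1 and 1 for lists of other tissues and later cell types. For pathways and control lists it was Notch pathway 5 and 5, Hedgehog pathway 1 and 1, Wnt pathway 5 and 5, Fgf pathway 2 and 3, immediate early and stress 1 and 0, housekeeping 6 and 7, RNA without poly(A) tail 2 and 2. Over all 18297 genes tested, 23.5% were called. Mesenchyme (3 of 13 tested) lay near that share, cell cycle (10 of 19) above it and Hedgehog (1 of 11) below it. The test weighs counting error alone, so the calls in a list also depend on the depth of its members.

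**Figure D3:**
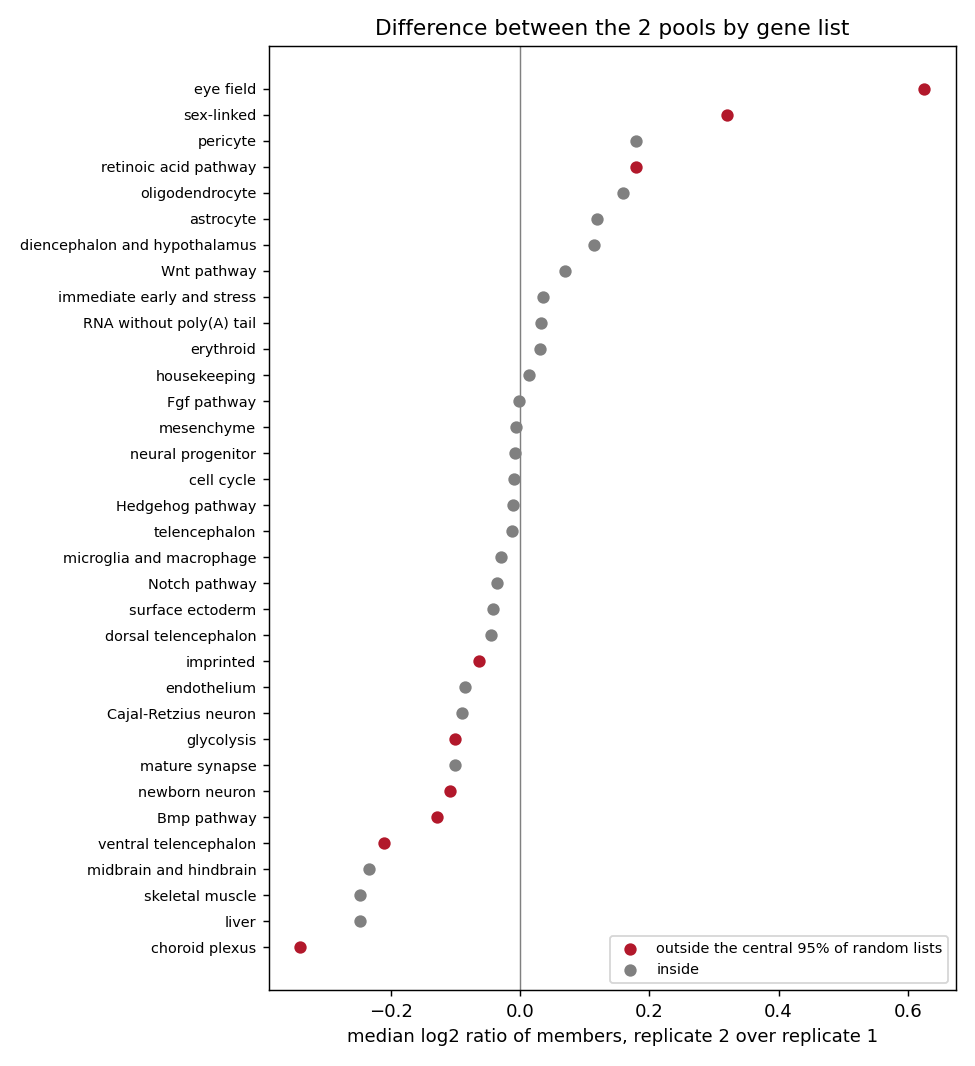
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis) for the members of 34 gene lists (vertical axis), with lists outside the central 95% of 10000 expression-matched random lists in red. The ventral telencephalon list lies at -0.21, newborn neuron at -0.11 and sex-linked genes at 0.32.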

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

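An entry with a numeric identifier, of a kind that no comparison used, carried counts in both libraries. Of 26248 such entries with a median length of 73 nucleotides, 11 had a count, and 1 had more than 3 counts in both libraries, the limit that a count of 0 allows per entry and library. That entry had 8 expected counts in replicate 1 and 8 in replicate 2. The series has no control libraries to compare it with, and no explanation was tested.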

How the results depend on the processing

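Each of the 4 list comparisons kept its direction and its side of the threshold under every alternative that gave a value, with differences of 4.57 to 11.84 log2 units for regional identity, 0.34 to 0.60 for dorsal against ventral, 0.05 to 0.76 for progenitor against neuron and 3.04 to 4.04 for newborn against mature neuron. Regional identity could not be computed on members with TPM of 1 or more, since no HOX gene was left. The replicate correlation moved from 0.984 to 0.951 with a pseudocount of 0.1, 0.894 with 0.01, 0.994 without a filter and 0.994 over protein-coding genes only, and the cause was not tested. The library difference count of 481 genes fell to 183 with 50 or more counts summed, 262 over protein-coding genes and 207 with non-overlapping credibility intervals. It was 254 over genes with whole expected counts, chosen after seeing the data. Fewer genes were tested under the filters, but the share called at 2-fold or more also fell. It was 2.63% in the main run, 1.24% with 50 or more counts and 1.75% over protein-coding genes. The cause was not tested for the filters or for the intervals. Protein-coding class share was 89.4% of expected counts, since TPM divides by length. Genes detected stayed within 1.5 times of 14241, dispersion ranged from 6.96% to 7.65%, and lists outside the central 95% from 8 to 11. The number of genes whose leading transcript differed, 454, was 133 with gene TPM of 50 or more, where fewer genes were tested. Matching random lists on GC, chosen after seeing the data, brought the diencephalon and hypothalamus, oligodendrocyte, pericyte and Wnt lists outside the central 95% and the Bmp and imprinted lists inside it. Leaving out a library gave no isoform discordance and no library difference, which need both. The 9 lists outside the central 95% and the log2 ratios of the 20 named genes kept their direction under every alternative run for them. Among lists inside it, with 50 or more counts the astrocyte list went from 0.12 to -0.13, surface ectoderm from -0.04 to 0.12 and RNA without poly(A) tail from 0.03 to -0.02, and the Fgf list, near 0, changed sign with DESeq2 size factors. By transcript expected counts 13 shares of named isoforms moved by more than the spread between replicates, and by posterior mean TPM 54 single-gene TPM did. No paired analysis was possible because the series has a single group. Depth limits genes under 100 counts, where 95% of log2 ratios lay within 2.16 of 0.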

Other observations

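The values in this paragraph were picked after they were seen, and no explanation of them was tested. Some abundant RNAs lay outside the protein-coding genes. Gm42418 reached 8209 ± 288 TPM and its neighbour Gm26917 3140.0 ± 165 TPM (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788 and ENSMUSG00000097971.3, chromosome 17, 39843013 to 39846341, GRCm38). The RefSeq table used here lists Gm42418 as another name of Rn18s-rs5, an 18S ribosomal RNA related sequence, and together they took 1.48% ± 0.0107 of expected counts. The signal recognition particle RNAs Rn7s1 and Rn7s2, a near-identical pair, had 4108 ± 202 TPM and 4108 ± 202 TPM. Malat1, a nuclear RNA, was higher in replicate 2 (log2 ratio 0.36), as were the long imprinted RNAs Kcnq1ot1 (0.28) and Rian (0.19), while Meg3 stood at -0.03 and Xist was lower (-0.17). The hypothalamic factor Nkx2-4 was higher in replicate 2 (1.58), while of the oligodendrocyte list Olig2 was lower (-0.44) and Olig1 higher (0.46), the latter overlapping a gene on the opposite strand. The most abundant identifier without an M21 match had 3 transcripts that M21 places in Hnrnpu, and held 34.4% of the counts on unmatched identifiers.

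The test of shared reads was chosen after the result was seen. All 10 genes that differed 4-fold or more between the libraries with 100 or more counts had expected counts that were not whole (100%), against 28.6% of 13500 other genes at that depth (Fisher's exact test, p = 3.74e-06). A candidate explanation is that reads shared between near-identical genes were divided differently in each library. At 2-fold or more the share was 43.2% of 74 genes, so shared reads do not cover that wider set. No biological explanation was tested.

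The test here was chosen after the values were seen. Ventral telencephalon genes were lower in replicate 2 as a list, with a median of -0.21 and 11 of 14 members lower. GC content was argued against, since the median stayed at percentile 0.01 of random lists matched on expression and GC, although GC was correlated with the log2 ratio (Spearman rho -0.39 across 10164 protein-coding genes, which are not independent replicates). A difference between the pools in the share of neurons, in dissected ventral tissue or in stage is not analysed here and stays open.

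The GC test was chosen after its inputs were seen, while the tests of unspliced RNA and genomic DNA were written down before they were computed. TEC loci were higher in replicate 2, with 171 of 217 loci of 50 or more counts above 0 and a median log2 ratio of 0.33. GC content was argued against as the whole cause, since that median lay at percentile 100 of lists of protein-coding genes matched on expression and GC, which had a median of 0.04. More unspliced RNA in replicate 2 cannot be told apart from no such difference, because loci inside protein-coding genes on the same strand exceeded loci outside by 0.14 but did not pass the test (two-sided permutation p = 0.0827). Genomic DNA in replicate 2 also stays open: 1305 near-silent protein-coding genes had 1.05 times the scaled counts in replicate 2 (95% exact binomial interval 0.990 to 1.11), which is below the median TEC ratio of 1.25, but these genes had a median of 2 counts summed and lie too near the floor to exclude it, and no biological explanation was tested.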
